A study of Homo sapiens with 22 samples.

How the data were processed

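ChIP-seq libraries were made from VCaP and LNCaP cells that had been exposed to lentivirus for 48 h and then selected, for 8 days in VCaP with puromycin and for 4 days in LNCaP with blasticidin, per the labels' protocols. Crosslinking lasted 10 min in 1% formaldehyde, and sequencing gave single-end reads of 75 bp, per the labels' protocols. The 22 samples comprised 16 with a peak list and 6 input samples, whose reads were not analysed here. Groups were taken from the sample titles, and each combination of cell line, construct and antibody held 1 library.

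Reads were processed with Bowtie2 2.1.0, MACS2 2.1.0 and SAMtools against hg19, per the submitters' processing notes, which name the tools without their settings. Peaks were called per library and not pooled, as the authors deposited 1 list per library. Whether an input served as control in each call is not given in the sources used here. The 12 ERG and BAF155 lists were narrow peaks with a summit, and the 4 histone lists were broad regions. Per the columns the authors deposited, each peak carries a fold over background, a −log10 p and a −log10 q, and a whole-number score. The fold enrichment is the authors' linear ratio at the summit, or over the region for broad peaks. The deposited score is 10 times the −log10 q, rounded down, in nearly every peak. The lowest −log10 q in the deposited narrow lists was close to 3. All of these values belong to the authors' peak calling, depend on depth (the fold through its pseudocount), and were used here only to rank, bin or filter peaks within a list or to recover pileups.

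Peak names in the deposited lists are numbered with gaps, so peaks had been removed after calling by a filter that is not given in the sources used here. The missing numbers made up between 0.270% and 3.28% of a list, except in the ERG list of the LNCaP Empty line, where 962 of 1134 numbers (84.8%) were missing. In 26 of 28 comparisons between lists, at most 0.699% of the sites without a call in the other list lay where that list's numbers were missing. In the other two comparisons, those against the ERG list of the LNCaP Empty line, the shares were 45.2% of the unshared ERG sites of the ERG line and 45.9% of those of the R367K line, although at most 962 peaks can have been removed there.

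A site counted as called in another list when it shared at least 1 bp with one of its peaks. Shares of sites are given with Wilson 95% intervals, which cover the counting of sites only, since neighbouring sites are not independent and no group was repeated. No significance test was run and no p-value is given. The chance level of an overlap is the mean over 100 circular shifts of the compared list within each chromosome. Shifted peaks fall at any position, so this level takes no account of where chromatin is open. Stronger peaks are called again more often in any library, so differences between bound and unbound sites were averaged over 10 equal bins of the authors' −log10 q, with a normal 95% interval from counting. Differences between lists at the same sites have a normal 95% interval from the sites called in only 1 of the lists compared. The position among 10000 random site sets of the same size drawn within those bins is given as a description.

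Depth was read from the lists themselves, since read totals were not used here. From the deposited fold and −log10 p of each narrow peak, the pileup and the local background were solved under the Poisson model of the peak caller with a pseudocount of 1. The pileup came out whole, within 0.05, for 100% of peaks in each of the 12 narrow lists. The lowest background of a list stands for its genome-wide level and so for its relative depth. For comparisons at equal depth, pileups and backgrounds of the deeper library were scaled to the shallower one and peaks were kept at a Poisson −log10 p of 8 or more. To compare BAF155 pileups of sites called in both libraries, each was divided by its list's lowest background. The median log2 ratio was taken in each of 10 bins of mean BAF155 strength, for ERG-free sites and for 3 equal classes of ERG strength. ERG strength was here the ERG pileup over its list's lowest background, not the −log10 q. Medians were averaged over the bins by number of sites, with standard errors from 100 bootstrap draws of sites.

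The named sites follow a rule fixed before the data were examined. It was applied to the lists of each line against those of its control line (shCt or Empty) for the same antibody, apart from the ERG list of R367K against that of Empty, and to the ERG list of the ERG line against that of R367K. The 10 sites with the highest authors' −log10 q were taken from the direction with more unshared sites, and from both directions in the last of these comparisons. Coordinates are hg19 and counted from 1. No annotation or sequence of hg19 was used here, so sites are given by coordinates without genes, and 13 gene lists, motif searches and distances to genes that had been planned were not run. ERG sites in the strongest 10% were further divided by the knockdown in which they were called, and VCaP site classes were looked up in the LNCaP lists, after values had been seen.

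The procedures were tested on simulated data. All 7000 partners simulated among 20000 sites were found. A difference of 12 percentage points simulated in 80000 sites whose class went with strength came out at 11.5 with the bins and at 21.4 without them. Strength was constant within each simulated bin, so the simulation does not show how much difference in strength stays inside the bins of the data. Of 3779 simulated summits, 99.95% gave back their pileup. Alternatives were a −log10 q of 5 or more, summits within 250 bp of each other, lists of equal length, no bins of strength and scaled depth. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.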

Results

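Binding of the ETS transcription factor ERG and of BAF155, a core subunit of the BAF (mammalian SWI/SNF) chromatin remodelling complexes encoded by SMARCC1, was mapped by ChIP-seq in 2 prostate cancer cell lines. VCaP cells carry the TMPRSS2-ERG fusion and express ERG. They received a control hairpin (shCt), a hairpin against ERG (shERG) or a hairpin against ARID1A (shARID1A), a subunit found in the canonical form of the complex. LNCaP cells lack an ERG fusion and received an empty vector (Empty), ERG, or ERG-R367K, in which an arginine of the DNA-binding ETS domain is replaced by lysine. Each of these 6 lines had 1 ERG and 1 BAF155 library. The LNCaP Empty and ERG lines also had 1 library each for H3K27ac, a mark of active promoters and enhancers, and for H3K27me3, the mark laid down by Polycomb.

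The lists held between 22528 and 112232 ERG peaks in the VCaP lines and the LNCaP ERG and R367K lines, and 172 in LNCaP Empty. BAF155 lists held between 56200 and 92498 peaks, H3K27ac lists 45370 (Empty) and 43579 (ERG) regions, and H3K27me3 lists 28991 and 34039 regions. The lowest background pileup, a measure of relative depth, was 1.24 for ERG in shCt, 1.18 in shERG and 1.05 in shARID1A. It was 1.59, 2.03 and 1.63 for BAF155 in the same lines. In LNCaP it lay between 1.94 and 2.35 for all BAF155 libraries and for ERG in the ERG and R367K lines, and at 0.490 for ERG in Empty. No group had a replicate, so no difference could be set against a spread between libraries. Intervals are 95% intervals that cover the counting of sites only, Wilson intervals for shares and normal intervals for differences. Fold and −log10 q per peak are the authors' values.

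**Figure D1:**
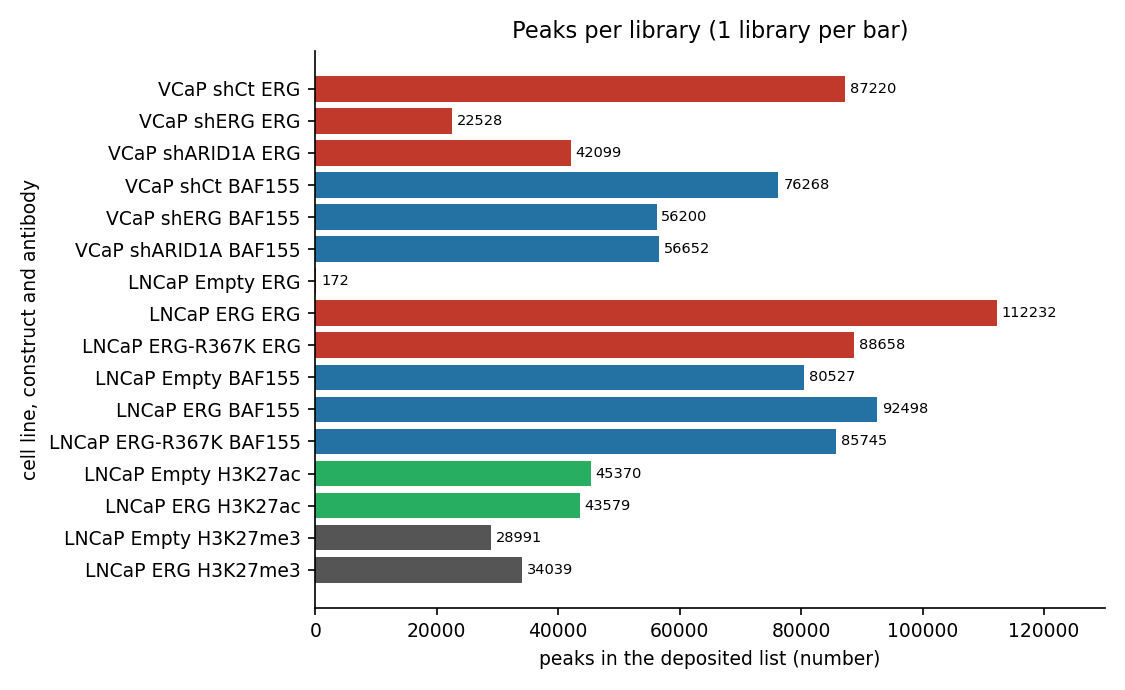
Peaks per deposited list (x axis, number of peaks) for each cell line, construct and antibody, 1 library per bar. ERG peaks numbered 87220 in VCaP shCt, 22528 in shERG and 42099 in shARID1A, and 172 in LNCaP Empty against 112232 in the ERG line.

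The first question was how many ERG sites of shCt were also called under each of the other hairpins in VCaP. Of the 87220 ERG sites of shCt, 21710 (24.9% [24.6 to 25.2], chance 0.604%) were called in shERG and 39553 (45.3% [45.0 to 45.7], chance 1.22%) in shARID1A. Hardly any site appeared: 99.3% of the shERG calls and 96.3% of the shARID1A calls lay at shCt sites. Calls were missing mainly at weak sites: the share called in shERG went from 0.527% in the weakest 10% of sites to 96.2% in the strongest, and in shARID1A from 9.20% to 98.0%. The strongest shCt sites with no call in shERG lay on chromosome 11 at 121330203 to 121330714 (fold 57.4, −log10 q 301.4), on chromosome 20 at 48763389 to 48763879 (fold 54.7) and on chromosome 1 at 62458692 to 62459703 (fold 51.0). All 10 named sites of this comparison had ERG in shARID1A, BAF155 in shCt and ERG in the LNCaP ERG line. With lists shortened to equal length by −log10 q, 75.9% of sites were shared between shCt and shERG and 73.5% between shCt and shARID1A. At equal depth, 25.1% of shCt sites were called in shERG and 46.3% in shARID1A, whose ERG library was 1.18 times shallower than that of shCt. Weaker enrichment of the ERG libraries of the knockdowns was not tested, so a missing call need not mean that ERG had left the site.

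ERG and BAF155 occupied largely the same places in control VCaP cells. BAF155 was called at 58742 of the ERG sites (67.3% [67.0 to 67.7], chance 2.16%), and ERG at 59310 of the 76268 BAF155 sites (77.8% [77.5 to 78.1]). The chance level takes no account of open chromatin, which the lists may share. BAF155 was called at 43.7% of the weakest 10% of ERG sites and at 97.6% of the strongest 10%. Of the 22528 ERG peaks of shERG, 87.9% lay at BAF155 sites of shCt.

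ERG knockdown left most BAF155 sites in place. Of the 58742 ERG sites with BAF155 in shCt, 28.0% had both calls in shERG, 41.5% had BAF155 without ERG and 25.6% had neither. Of the BAF155 sites of shCt, 63.3% [63.0 to 63.6] were called in shERG and 62.5% [62.1 to 62.8] in shARID1A. The shERG BAF155 library was 1.27 times deeper than that of shCt, yet held fewer peaks. Its median pileup over the lowest background was 15.8, against 20.1 in shCt and 18.4 in shARID1A. Weaker enrichment may thus account for some of the calls missing in shERG. Sites with ERG kept BAF155 more often than sites without it, at 69.0% [68.7 to 69.4] against 43.3% [42.5 to 44.0] in shERG and at 69.6% [69.2 to 70.0] against 37.5% [36.8 to 38.2] in shARID1A. ERG-bound sites were also the stronger BAF155 sites. Averaged over the bins of strength, the difference was 3.43 percentage points [2.57 to 4.29] in shERG and 13.0 [11.9 to 14.0] in shARID1A, against highest values of 1.61 and 1.68 among random site sets. Differences in strength inside a bin were not removed, and the random sets do not measure them. Without the bins of strength these were 25.8 and 32.1 points, with summits within 250 bp they were 1.52 and 8.33, and at equal depth the shERG value was 1.61.

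Counting gained as well as lost BAF155 calls, a count added after the data had been seen, set ERG-bound apart from ERG-free sites. At ERG-bound sites, 18362 BAF155 calls of shCt were missing in shERG and 2329 were new there, which is 7.88 lost per gained call, while ERG-free sites had 9622 lost and 5274 new (1.82). In shARID1A the corresponding ratios were 5.01 at ERG-bound and 1.70 at ERG-free sites. The strongest BAF155 sites absent from shERG lay on chromosome 9 at 116882306 to 116883030 (fold 34.7) and on chromosome 11 at 130521148 to 130521567 (fold 28.5). All 10 named sites of that comparison carried ERG in shCt, 2 had ERG in shERG and 9 had ERG in shARID1A, where all 10 kept BAF155. The bound-to-free ratio of lost per gained calls was 4.32 in shERG with the ERG sites of shCt, against 2.95 in shARID1A. With ERG sites taken from the LNCaP ERG line it was 1.49 in shERG and 1.94 in shARID1A, so the order of the knockdowns turned.

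**Figure D2:**
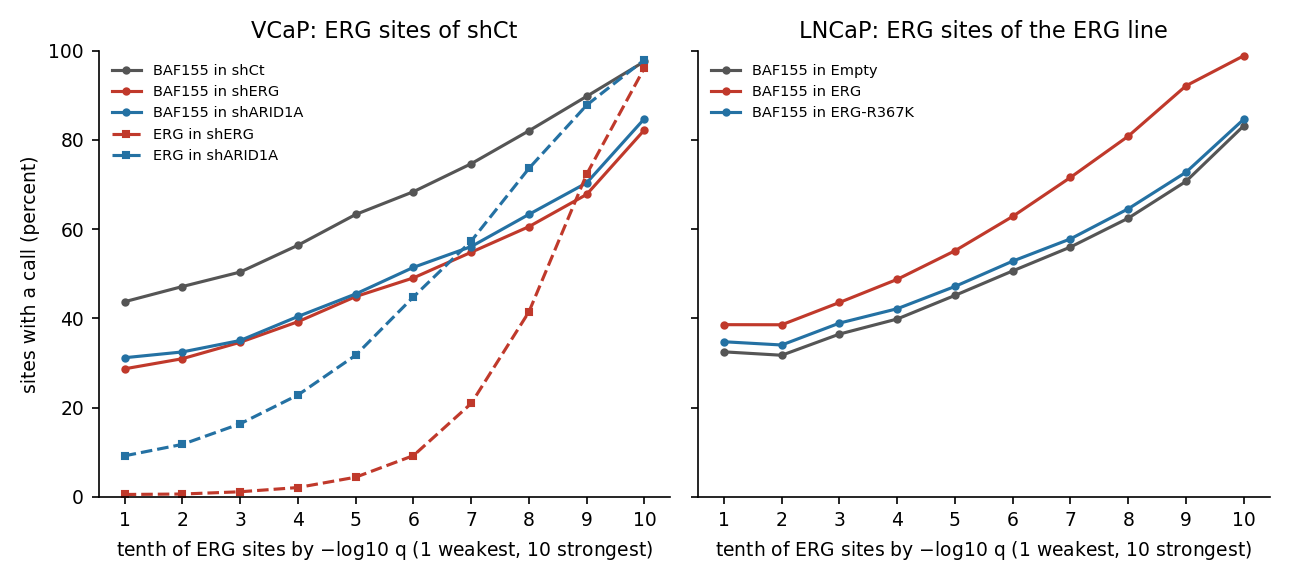
Percent of ERG sites with a call in another list (y axis) in 10 equal classes of ERG strength from the authors' −log10 q (x axis, 1 weakest), for ERG sites of VCaP shCt (left) and of the LNCaP ERG line (right). In the strongest 10% of VCaP sites, BAF155 was called at 97.6% in shCt, 82.3% in shERG and 84.8% in shARID1A, while ERG was still called at 96.2% in shERG. In the strongest 10% of LNCaP sites, BAF155 was called at 83.2% in Empty, 98.9% in the ERG line and 84.6% in R367K.

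At the few strong ERG sites that kept ERG in 1 knockdown only, BAF155 calls went with the ERG calls of the same knockdown. Of 8513 sites in the strongest 10% with BAF155 in shCt, 8052 kept ERG in both knockdowns, and BAF155 was called at 86.4% of them in shERG and 88.0% in shARID1A. The 293 sites with ERG in shARID1A and not in shERG had BAF155 at 71.7% [66.3 to 76.5] in shARID1A and 33.1% [28.0 to 38.7] in shERG. The reverse held for the 141 sites with ERG in shERG and not in shARID1A, with BAF155 at 63.1% [54.9 to 70.6] in shERG and 10.6% [6.55 to 16.8] in shARID1A. One site on chromosome 15 was among the named sites for both antibodies: ERG at 90352368 to 90352831 (fold 39.4) and BAF155 at 90352336 to 90352807 (fold 23.3) were called in shCt and shERG, and neither was called in shARID1A. Across all 58742 sites the same split gave 68.6% in shERG against 88.5% in shARID1A where ERG was called in shARID1A alone, and 77.6% against 31.9% where it was called in shERG alone. This division was chosen after values had been seen.

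**Figure D3:**
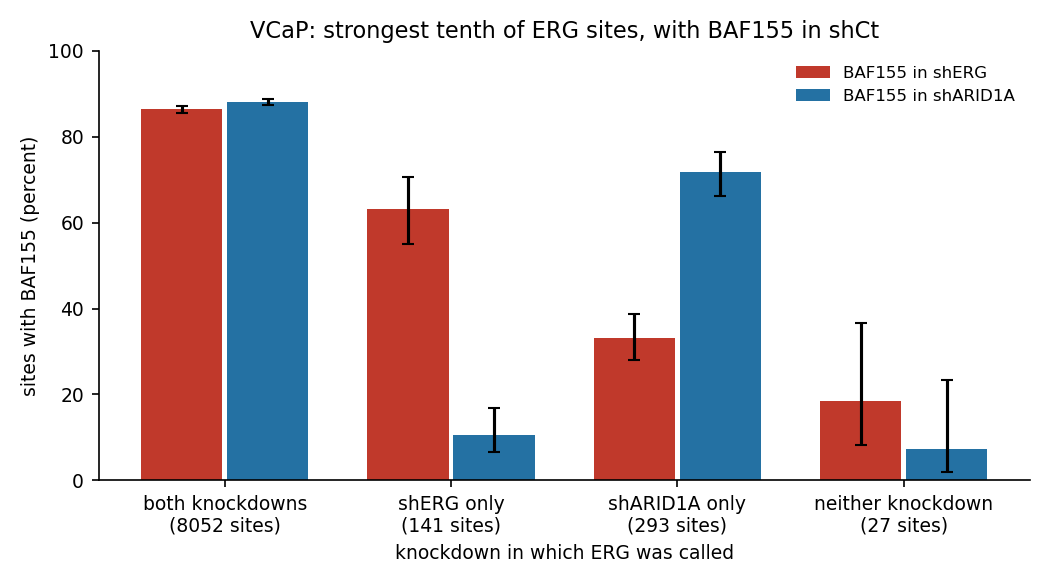
Percent of VCaP ERG sites with BAF155 (y axis) in shERG (red) and shARID1A (blue), for the strongest 10% of ERG sites with BAF155 in shCt, grouped by the knockdown in which ERG was called (x axis, with the number of sites); error bars are Wilson 95% intervals. BAF155 was at 33.1% in shERG and 71.7% in shARID1A where ERG was called in shARID1A only, and at 63.1% and 10.6% where ERG was called in shERG only.

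ERG calls of shCt were missing in shARID1A less often where BAF155 had been called. ERG sites with BAF155 in shCt were called in shARID1A at 56.1% [55.7 to 56.5] and those without at 23.1% [22.6 to 23.6]. Averaged over the bins of ERG strength, the difference was 9.46 percentage points [8.80 to 10.1], against a highest value of 1.12 among random site sets. The same split in shERG gave 33.0% with BAF155 and 8.23% without. Averaged over the bins that difference was 1.86 points [1.26 to 2.47], against a highest random value of 1.18. Differences in ERG strength inside a bin were not removed. Strong shCt ERG sites absent from shARID1A included chromosome 5 at 142254103 to 142254644 (fold 40.6) and at 57541044 to 57541680 (fold 55.6). All 10 named sites of this comparison had BAF155 in shCt and ERG in shERG, 8 had BAF155 in shERG and 1 had BAF155 in shARID1A. In shARID1A the difference was 33.0 points without the bins of strength and 6.08 with summits within 250 bp.

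Among the strongest BAF155 sites absent from shARID1A were chromosome X at 66993851 to 66994365 (fold 7.73, −log10 q 139.5) and chromosome 3 at 30559703 to 30560321 (fold 16.5). All 10 named sites of that comparison had ERG in shCt and BAF155 in shERG, 8 had ERG in shERG and 5 had ERG in shARID1A.

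In LNCaP, the ERG construct gave ERG calls across a broad set of sites that were not called in the Empty line. The ERG line had 112232 ERG sites, of which 31 (0.0276% [0.0195 to 0.0392]) were called in Empty, whose own list held 172 peaks. The strongest sites were on chromosome 3 at 193851562 to 193854329 (fold 77.1, −log10 q 558.5) and chromosome 12 at 106327622 to 106328793 (fold 62.3), and all 10 named sites were also ERG sites of VCaP shCt. The Empty ERG library was 4.01 times shallower than that of the ERG line and 962 of its peak numbers were missing, so its list understates what that library held.

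The ERG library of the R367K line gave calls at many sites, and these were mainly BAF155 sites. The R367K line had 88658 ERG peaks, and 62187 of the ERG sites of the ERG line (55.4% [55.1 to 55.7], chance 2.48%) were among them. BAF155 of the Empty line was already called at 79.1% [78.9 to 79.4] of the R367K ERG sites, against 50.9% [50.6 to 51.2] of the ERG sites of the ERG line. Conversely, 87.2% of the BAF155 sites of Empty had an ERG call in the R367K line. Where the R367K list had no call, at 50045 sites of the ERG line, BAF155 of Empty was called at 7.12% [6.89 to 7.34], compared with 86.1% [85.8 to 86.4] where it had one. ERG sites strong in the ERG line and absent from R367K included chromosome 3 at 187946539 to 187947587 (fold 60.4) and chromosome 5 at 75979826 to 75980865 (fold 68.2). None of those 10 named sites had BAF155 in Empty, 10 had it in the ERG line and 1 in R367K. The 10 named sites of the other direction, such as chromosome 21 at 37727995 to 37728611 (fold 21.8), had BAF155 in all 3 LNCaP lines. Pileups were compared at the 52326 BAF155 sites of Empty that were also called in both R367K lists and in the ERG list of the ERG line. There the pileup of this ERG library had a Pearson r of 0.83 with BAF155 of the same line and 0.39 with ERG of the ERG line, so whether it holds ERG-R367K binding is open.

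At the ERG sites of the ERG line, BAF155 was called more often in that line than in Empty, and the R367K line lay close to Empty. Of the ERG sites, 50.9% had BAF155 in Empty, 63.1% [62.8 to 63.4] in the ERG line and 53.0% [52.7 to 53.3] in R367K, differences from Empty of 12.2 points [12.003 to 12.4] and 2.096 points [1.93 to 2.27]. In the strongest 10% of ERG sites the shares were 83.2%, 98.9% and 84.6%. At the ERG sites of the R367K line itself, BAF155 was called at 79.1% [78.9 to 79.4] in Empty and 84.4% [84.1 to 84.6] in R367K. At ERG-bound sites 16194 BAF155 calls were new in the ERG line and 1899 were missing (8.53 gained per lost), and at ERG-free sites 6260 were new and 7583 missing (0.826). For R367K against Empty, the gained per lost calls were 1.65 and 1.61 with the ERG sites of the ERG line, and 2.26 and 1.17 with the ERG sites of the R367K line itself. With ERG sites of VCaP shCt, the ERG line had 6.28 gained per lost call at bound and 1.55 at free sites, so the bound-to-free ratio was 4.04 in place of 10.3. With ERG sites of the R367K line the order turned, at 1.77 gained per lost call at bound and 2.99 at free sites (ratio 0.592). The strongest new BAF155 sites lay on chromosome 9 at 22158865 to 22159425 (fold 30.5) and chromosome 10 at 52528137 to 52529070 (fold 31.6), and all 10 named ones were ERG sites in both the LNCaP ERG line and VCaP shCt. With BAF155 lists shortened to equal length the ERG difference was 7.02 points and the R367K difference 0.0454 points, an interval of −0.127 to 0.217, while at equal depth the R367K difference was 3.31 points.

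H3K27ac was compared at ERG sites grouped by their BAF155 calls. At the 15529 ERG sites with BAF155 in the ERG line and not in Empty, H3K27ac was called at 25.5% [24.8 to 26.2] in Empty and 33.5% [32.8 to 34.3] in the ERG line, a difference of 7.99 points [7.40 to 8.57]. Of these sites, 4496 (29.0%) also had BAF155 in R367K, so the class is not particular to the ERG line. Where BAF155 was called in both lines (55289 sites), H3K27ac was at 62.1% and 60.9%, where it was called in neither (39602 sites), at 11.96% and 13.6%, and where it was called in Empty only (1812 sites), at 28.2% and 25.3%. The H3K27ac difference also went with ERG strength, from −1.09 points in the weakest 10% of ERG sites to 7.71 in the strongest 10%, where 83.2% had BAF155 in Empty, and the classes were not compared at equal ERG strength. H3K27me3 was rare at ERG sites, at 1.02% in Empty and 0.880% in the ERG line against chance levels of 1.97% and 2.33%. At the sites with new BAF155 it was called at 148 sites in Empty and 90 in the ERG line, a difference of −0.373 points [−0.500 to −0.247]. With a −log10 q of 5 or more in every list, the H3K27ac difference was 4.38 points and the H3K27me3 difference −0.0324 points, with an interval of −0.0706 to 0.00570.

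**Figure D4:**
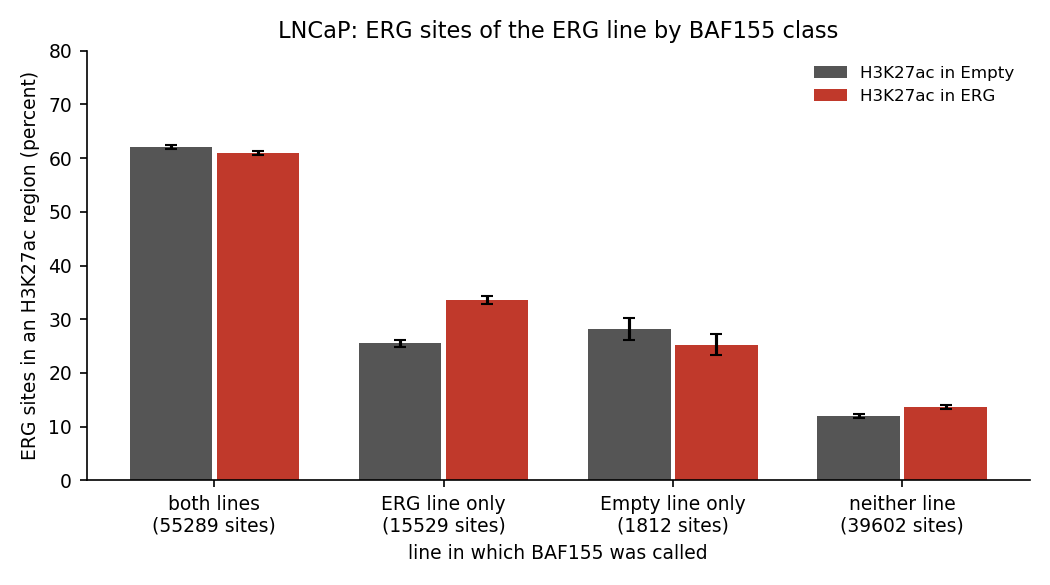
Percent of LNCaP ERG sites inside an H3K27ac region (y axis) in Empty (grey) and in the ERG line (red), by the line in which BAF155 was called at the site (x axis, with the number of sites); error bars are Wilson 95% intervals. At sites with BAF155 in the ERG line and not in Empty, whatever the call in R367K, the share was 25.5% in Empty and 33.5% in the ERG line.

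The named regions of the histone marks were set beside the share of all regions that held an ERG site. The strongest H3K27ac regions of Empty with no call in the ERG line included chromosome 10 at 80849501 to 80849927 (fold 5.51), and 1 of the 10 was at an ERG site of the ERG line. Of all 45370 H3K27ac regions of Empty, 29598 held such a site, but these were called again in the ERG line at 90.2%, against 45.7% of the others. The strongest H3K27me3 regions of the ERG line with no call in Empty were all on chromosome 5, such as 111601214 to 111601856 (fold 3.95), and none of the 10 overlapped a peak in any ERG or BAF155 list. Only 864 of all 34039 H3K27me3 regions of the ERG line held an ERG site, so none among 10 lies near that share.

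ERG sites were shared between the lines that carry the fusion and the lines that received ERG. Of the LNCaP ERG sites, 54.2% [53.9 to 54.5] were ERG sites in VCaP shCt (chance 2.55%), and of the VCaP sites 70.8% [70.5 to 71.1] were ERG sites in LNCaP. The share was 93.6% in the strongest 10% of LNCaP ERG sites and 25.7% in the weakest 10%. BAF155 sites of VCaP shCt were BAF155 sites of LNCaP Empty at 60.4% [60.1 to 60.8].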

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

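Scaling to equal depth and the ratio of lost to gained calls were chosen after the data had been seen; the other settings were fixed before the data were examined. Of 51 alternative values for the 12 planned results and that ratio, 29 of the 39 planned and 8 of the 12 added ones moved by more than the interval of the main value. None changed sign, but shares and the ratio are always positive, so only the differences could have done so. No paired analysis was possible because each group held 1 library of each antibody. The alternative windows planned for gene lists, motifs and distance to genes were not run, since no annotation or sequence of hg19 was used. Comparisons with the Empty ERG list are limited by its depth (lowest background 0.490) and by its 962 missing peak numbers.

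With a −log10 q of 5 or more, BAF155 lay at 66.9% of VCaP ERG sites, and the BAF155-bound minus BAF155-free difference of ERG calls in shARID1A was 8.78 points. Then 55.1% of LNCaP ERG sites were called in R367K, and at sites with new BAF155 the H3K27ac difference was 4.38 points and the H3K27me3 difference −0.0324 points. With summits within 250 bp, 24.5% of VCaP ERG sites were called in shERG and 44.1% in shARID1A, and 63.4% had BAF155. The ERG-bound minus ERG-free differences of BAF155 calls were then 1.52 (shERG) and 8.33 points (shARID1A), and that of ERG calls by BAF155 was 6.08. In LNCaP, 52.3% of ERG sites were called in R367K and 52.0% in VCaP shCt, BAF155 at ERG sites exceeded Empty by 11.8 (ERG) and 1.78 points (R367K), and the H3K27ac difference was 6.81 points.

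With lists of equal length, which hold the stronger sites only, 75.9% (shERG) and 73.5% (shARID1A) of VCaP ERG sites were shared, and 97.1% of the strongest 10000 had BAF155. The split differences were 2.52 points for BAF155 in shERG and 10.2 for ERG in shARID1A. In LNCaP, 60.6% of ERG sites were called in R367K and 62.0% in VCaP shCt, and the differences were 7.02 (BAF155, ERG), 0.0454 (BAF155, R367K) and 9.75 points (H3K27ac). Without bins of strength the 3 split differences were 25.8, 32.1 and 33.0 points, because bound sites are stronger. At equal depth, 46.3% of VCaP ERG sites were called in shARID1A, 63.3% had BAF155, and the shERG split was 1.61 points. LNCaP ERG sites were called in R367K at 54.2% and in VCaP shCt at 57.5%, and BAF155 in R367K exceeded Empty by 3.31 points. The bound-to-free ratio of lost per gained BAF155 calls in shERG was 4.76 at equal depth and 1.49 with ERG sites of the LNCaP ERG line. For the threshold, summit, depth and LNCaP settings the cause was not tested.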

Other observations

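The tests of library enrichment at equal BAF155 strength and the comparison of the ERG with the R367K construct were chosen after the results were seen, as were the count of lost per gained calls and the site classes carried from VCaP to LNCaP. Of the BAF155 sites of VCaP shCt that had ERG and were not called in shERG (18362 sites), 35.8% [35.1 to 36.5] had BAF155 in LNCaP Empty, 51.3% [50.6 to 52.0] in the LNCaP ERG line and 39.2% [38.5 to 39.9] in R367K. The ERG-free BAF155 sites not called in shERG (9622 sites) had BAF155 at 36.4% [35.4 to 37.4], 39.7% [38.7 to 40.7] and 40.1% [39.2 to 41.1] in the same lines. At 2909 sites, ERG was called in both cell lines and BAF155 was absent from VCaP shERG, absent from LNCaP Empty and present in the LNCaP ERG line. The 293 strong VCaP ERG sites with ERG in shARID1A and not in shERG had BAF155 at 30.0% [25.1 to 35.5] in LNCaP Empty, 60.1% [54.4 to 65.5] in the ERG line and 31.4% [26.4 to 36.9] in R367K. This rise was not particular to sites whose ERG call was missing in shERG. The 141 strong sites with ERG in shERG alone went from 53.9% in Empty to 78.7% in the ERG line, and the 27 with ERG in neither knockdown from 33.3% to 59.3%. Over all sites, those with ERG in shERG alone went from 66.1% to 77.0%, and those with ERG in shARID1A alone from 61.7% to 70.1%.

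H3K27ac and H3K27me3 regions hardly overlapped: 20 of 45370 H3K27ac regions of Empty (0.0441%) overlapped H3K27me3. H3K27ac regions of Empty that held an ERG site of the ERG line were called again in the ERG line at 90.2%, against 45.7% of those without one, or 84.2% against 64.4% at equal region length. In the other direction, H3K27ac regions of the ERG line were called in Empty at 80.4% with an ERG site and 77.1% without at equal length, and at 69.9% with a new BAF155 site and 80.1% without. The strongest H3K27me3 regions gathered on chromosomes 5 and 4 in both lines. In the strongest 10%, chromosome 5 held 20.2% in Empty and 19.8% in the ERG line, against 6.32% and 6.19% of all H3K27me3 regions. Chromosome 4 held 16.1% and 19.3%, against 871 of 28991 and 1026 of 34039 of all regions, while for H3K27ac the strongest 10% had 6.96% and 7.30% on chromosome 5.

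ERG calls in the R367K line lay at BAF155 sites of the Empty line at 79.1%. Antibody background on open chromatin is argued against, since scaling to the depth of the Empty ERG library left 35058 R367K peaks against 166 in Empty, 211 times as many, and 30.9 times all 1134 peak numbers that Empty had before filtering. A BAF155 library under an ERG label stays open: across those 52326 shared BAF155 sites, which are not independent, R367K ERG pileup had a Pearson r of 0.83 with R367K BAF155 pileup and 0.39 with ERG pileup of the ERG line, although the BAF155 libraries of R367K and Empty reached 0.94 with each other. These sites leave out the 6585 R367K ERG peaks found in no LNCaP BAF155 list. Of those peaks, 30.5% were ERG sites of the ERG line, against 74.9% of R367K ERG peaks with BAF155 and a chance level of 3.18% for the whole list. The ratio of R367K ERG to R367K BAF155 pileup followed ERG pileup with an r only 0.0296 above that of the ratio of Empty to R367K BAF155 pileup. Mutant ERG held at BAF complexes without its own DNA contacts may give the same picture and was not tested separately.

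BAF155 pileup in the LNCaP ERG line relative to Empty went up with ERG strength, among sites called in both. At equal mean BAF155 strength, the strongest of 3 equal ERG classes lay 0.56 log2 (bootstrap SE 0.0126) above ERG-free sites, which argues against depth or enrichment of the library as the whole cause. With ERG strength taken from VCaP shCt the difference was 0.36, so it does not rest on the chromatin preparation of the ERG line alone, and it exceeded the difference in the R367K line by 0.54, which argues against delivery of an ERG construct alone but not against an effect of any ERG protein, since whether the R367K line held the mutant protein is open. No mechanism was tested, and a difference between single libraries of each line was not excluded, since no line was repeated.

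In VCaP shERG, BAF155 calls lost per call gained were 4.32 times higher at ERG-bound than at ERG-free sites. When ERG sites came from the LNCaP ERG line the ratio was 1.49, so a part that comes from taking ERG and BAF155 in the same cells cannot be told apart from one that depends on ERG. Weaker enrichment of the shERG BAF155 library also stays open. Among sites called in both libraries, BAF155 pileup was lower in shERG than in shCt in every class of VCaP ERG strength. The change was −0.32 log2 at ERG-free and −0.69 log2 at the strongest ERG sites, against 0.05 and −0.25 log2 in shARID1A. Strong ERG sites and ERG-free sites differed by −0.37 log2 in shERG with VCaP ERG strength but by −0.09 with LNCaP ERG strength. In shARID1A these differences were −0.31 and −0.01. The ratio in shERG was 1.46 times that in shARID1A with ERG sites of shCt, but with those of the LNCaP ERG line shARID1A had the higher ratio (1.94 against 1.49), so an effect shared by both knockdowns may account for much of it. Where ERG was called in shARID1A and not in shERG, BAF155 was called at 33.1% in shERG against 71.7% in shARID1A at 293 strong sites but at 68.6% against 88.5% over all 15508 sites, and these classes too come from the same cells as the BAF155 lists.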
